A study of Vanessa cardui with 14 samples.

How the data were processed

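RNA of developing wings of the painted lady butterfly, Vanessa cardui, was measured in 14 libraries of polyadenylated RNA. Whole hind wings were sampled at 1 larval stage (last instar) and 4 pupal stages, which were 72 h after pupation, 5 d after pupation before pigment was visible, the stage when red and orange ommochrome pigment began to appear, and the stage when black melanin began to appear. Red and black regions were dissected from pupal forewings. Each of these 7 groups had 2 libraries. The sample titles and stage labels place the forewing regions at the melanin stage, while the treatment protocol places their dissection at the ommochrome stage, so the forewing stage is given below as labelled and the conflict stays open.

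Libraries were made with a kit for poly-A RNA and sequenced as 150 bp paired-end reads on an Illumina HiSeq instrument, per the labels' protocols. Reads were aligned with Bowtie, per the submitters' processing notes, which give no version. The title of the series names a de novo transcriptome as the reference. The assembler, the program that made the expression values and any filter on genes are not given in the sources used here. The values deposited by the authors are FPKM (fragment counts divided by gene length and by the mapped fragments of the library), 1 column per library, rounded to 2 decimals. Whether the libraries were scaled further against each other is not given in the sources used here. FPKM are relative to the library total, so a rise of a few abundant genes lowers the values of all others.

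The table held 13876 genes, of which 72 were at 0 in every library. A gene here is an identifier made of an assembled component and a gene number within it. The 13876 genes came from 11105 components, and 4784 genes shared their component with another gene, so that reads could be divided between similar sequences and the values of such genes are less certain. The table pairs no identifier with a gene name, and 0 of the 13876 identifiers matched the reference gene table used here. The 18 lists of pigment, patterning, cuticle and cell type marker genes fixed beforehand could therefore not be applied. The check of the labels with Ultrabithorax, a gene known to be active in hind wings and inactive in forewings, could not be made for the same reason.

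Values were analysed as log2(FPKM + 1), and a log2 change on this scale understates the change of genes with low values. The 10780 genes with at least 1 FPKM in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3. A linear model with 7 group means was fitted to all 14 libraries with no covariate, which left 7 residual degrees of freedom, and the moderated test used a spread prior that followed the mean expression (2.88 prior degrees of freedom). All groups shared this estimate of the spread, because 2 libraries per group give too few degrees of freedom alone. The SD of the log2 difference between replicates was 1.19 at 72 h, against 0.429 to 0.725 in the other groups. The p-values of the steps to and from 72 h may therefore be too small, and those between quieter groups too large. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 10780 genes within each comparison, and a gene was called at an adjusted p under 0.05. The 6 comparisons were the 4 steps between successive hind wing stages, the black against the red forewing region, and the hind wing against the mean of both forewing regions at the labelled melanin stage. A moderated F test over the 4 steps gave the genes that changed across the 5 hind wing stages, and each was assigned to the stage of its highest mean. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

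With identifiers alone, at most 2 genes that rose and 2 that fell were named per comparison. They were those with the largest absolute log2 change among called genes with all libraries of the higher group above all of the other, and a mean of at least 5 FPKM in the higher group. This rule, the gene lists, the model, the comparisons and most alternatives were chosen before the data were examined.

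The total number of reads per library is unknown. The relative depth was estimated in Python 3.11.15 with NumPy 2.4.6 and pandas 2.3.3, because the low FPKM values of a gene fall on steps worth 1 read and the size of the step depends on the depth. Steps between 0.15 and 3 FPKM were compared for all 91 pairs of libraries, and 63 pairs lay within 0.1 log2 of the fitted depths. The estimate recovered the depths of 14 of 14 simulated libraries within 0.1 log2. Figures were drawn with matplotlib 3.10.9.

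Data were simulated from the mean over all libraries and the moderated spread of each of the 10780 genes, with the same spread in every group. The model was tested on these data with known changes, 100 of each size per comparison. Of changes of 1 log2, it recovered 12% for larva to 72 h, 6% for 72 h to 5 d, 9% for 5 d to ommochrome, 5% for ommochrome to melanin, 3% for black against red and 23% for hind wing against forewing. Of changes of 2 log2, it recovered 62%, 67%, 76%, 68%, 66% and 84% in the same order, with 1 to 10 false calls. The F test recovered 77.5% of 200 changes of 2 log2. All comparisons except hind wing against forewing had the same simulated setting, so their recovery differed by random draw alone. The real SD of the log2 difference between replicates ran from 0.429 in black regions to 1.19 at 72 h, which the simulation did not copy. It also held few changed genes, while 5632 real genes were called from larva to 72 h and 2337 from 72 h to 5 d. The threshold on p is looser where more genes are called, and real calls from larva to 72 h reached down to 0.506 log2. These percentages therefore do not give the recovery in real comparisons with many calls.

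Alternatives were other pseudocounts, filters on low values, scalings between libraries, a constant spread prior, fits to fewer groups, the replicate number as a block, a minimum log2 change, and each library left out in turn. Alternatives that needed gene names were not run.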

Results

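Expression of 13876 assembled genes was measured in 14 libraries from wings of the painted lady, a butterfly whose adult colours are laid down in the pupal wing, the red and orange ones as ommochromes and the black ones as melanin. Hind wings covered 5 stages from the last larval instar to the appearance of melanin, and forewings were divided into red and black regions, with 2 libraries in each of the 7 groups. The summed FPKM per library ranged from 482546 in ommochrome replicate 2 to 833658 in larval replicate 1. Relative to larval replicate 1, the estimated depth ranged from 0.929 to 1.9 in the other libraries except melanin hind wing replicate 1, at 0.461. That library listed 3641 genes at 0, against 1931 to 2707 in each of the others.

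The larval, 72 h and 5 d hind wings followed the order of development on the first principal component, while the ommochrome and melanin hind wings overlapped. This component held 42.8% of the variance and ran from the larval hind wings at -135.7 and -139.6, through 72 h at -72.6 and -52.43 and 5 d at -5.572 and 3.11, to ommochrome at 39.91 and 37.37 and melanin at 31.2 and 47.69. The forewing regions lay between 58.87 and 63.73. The third component, with 13.1% of the variance, placed the 4 forewing libraries at 35.09 to 35.86, the 72 h hind wings beyond them at 55.8 and 50.03, and the melanin hind wings at -45.14 and -24.42. Group means of the ommochrome and melanin hind wings had a Spearman correlation of 0.96 across genes, those of the red and black regions 0.979, and those of larval and melanin hind wings 0.669. Replicates differed most at 72 h, where the SD of the log2 difference between the libraries was 1.19, against 0.429 to 0.725 in the other 6 groups.

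**Figure D1:**
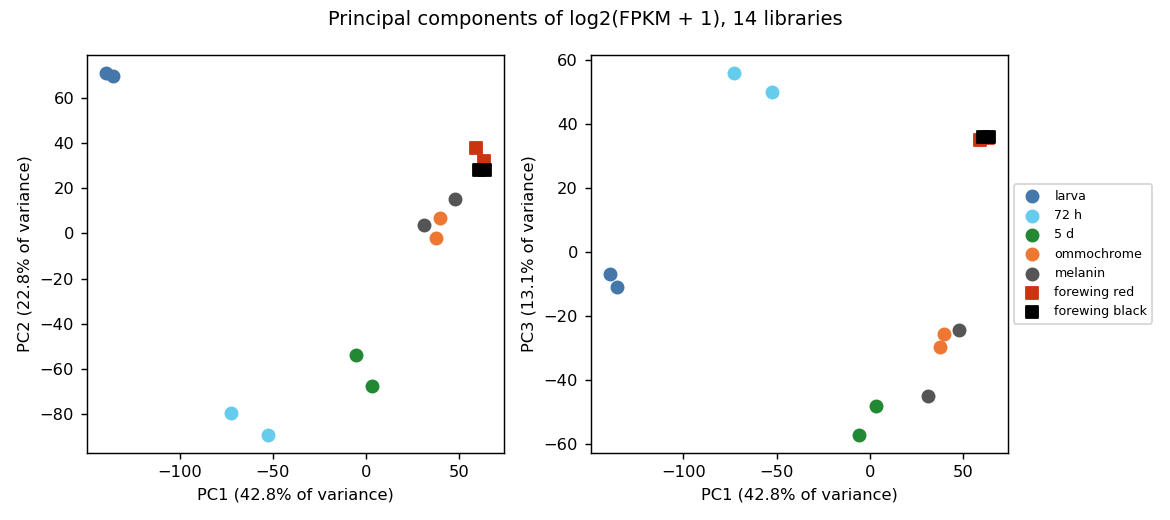
Scores of the 14 libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2(FPKM + 1), with the share of variance on each axis. Circles are hind wings and squares forewings, each point is 1 library, and the forewing libraries lie at 35.09 to 35.86 on component 3.

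Most genes of the hind wing changed during development. Across the 5 stages, 7624 of 10780 genes (70.7%) changed by the limma F test. Of these, 4815 (63.2%) were highest in the larva, 745 at 72 h, 477 at 5 d, 559 at the ommochrome stage and 1028 at the melanin stage. With median-of-ratios scaling 5738 genes changed and the larval share was 33%, with 1893 genes, against 1132 at 72 h, 932 at 5 d, 772 at the ommochrome stage and 1009 at the melanin stage. A smaller group had a mean of at least 5 FPKM at its peak and under 1 FPKM at every other hind wing stage. It held 75 larval genes, 38 genes of 72 h, 13 of 5 d, 1 of the ommochrome stage and 6 of the melanin stage.

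The step from the larval wing disc to the pupal wing at 72 h was compared first. The strongest rises began near the detection floor and ended among the most abundant transcripts. Gene c25543_g5 went from 0.78 and 0.99 FPKM in the larva to 1853 and 11019 at 72 h (log2 change 11.23, SE 0.725, limma adjusted p = 2.69e-06) and was back at 8.36 ± 1.29 (SD, n = 2) at 5 d. Gene c21563_g1 rose from 1.96 and 0.66 to 1171 and 7032 FPKM (log2 change 10.34, SE 0.64, adjusted p = 1.91e-06) and stayed at 273 to 399 FPKM on average in the later hind wing stages. In the other direction, c18780_g1 fell from 4403 ± 1219 to 0.205 ± 0.149 FPKM (log2 change -11.81, SE 0.843, adjusted p = 5.07e-06), and was measured at 732.1 and 297.7 FPKM at 5 d. Gene c18580_g1, at 3166 and 971.2 FPKM in the larva, was at 0 and 0.09 at 72 h (log2 change -10.71, SE 0.878, adjusted p = 1.13e-05).

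From larva to 72 h, 5632 genes changed, 831 higher and 4801 lower, and 315 rose and 429 fell by at least 3 log2. The median gene moved by -0.73 log2. The share of summed FPKM held by the 10 most abundant genes was 11.58% and 12.19% in the larval libraries and 33.69% and 31.86% at 72 h. The split depended on scaling: 1561 genes were higher and 1755 lower with median-of-ratios factors, and 1403 and 2096 with quantile normalization. It was 1267 and 1960 with the 10 most abundant genes of any library (51 genes) left out and totals made equal.

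The largest rises of the next step, from 72 h to the pre-pigment wing at 5 d, were of genes that became very abundant. Gene c27349_g2 went from 15.2 ± 17.1 to 30311 ± 2167 FPKM (log2 change 11.45, SE 1.1, adjusted p = 6.91e-05). Gene c19797_g1 went from 12.2 ± 7.98 to 31467 ± 5033 FPKM (log2 change 11.36, SE 0.664, adjusted p = 3.19e-06) and was still at 1808 ± 965.5 at the ommochrome stage. Over the same step c20598_g1 fell from 709.9 and 3700 FPKM to 1.29 ± 0.495 (log2 change -9.49, SE 0.703, adjusted p = 1.2e-05), and c21520_g2 fell from 5268 ± 1591 to 6.9 ± 1.17 FPKM (log2 change -9.36, SE 0.447, adjusted p = 1.39e-06). All 4 genes had under 11 FPKM in every forewing library.

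From 72 h to 5 d, 2337 genes changed, 1015 higher and 1322 lower, with a median shift of -0.14 log2. Of these, 262 rose and 152 fell by at least 3 log2. With median-of-ratios factors 1388 were higher and 1000 lower. With the 10 most abundant genes of any library left out and totals made equal, 1276 were higher and 946 lower. A fit to the hind wing libraries alone called 1526 genes.

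The step from 5 d to the ommochrome stage, when red pigment appears, switched on genes that then stayed high. Gene c162_g1 went from 5 ± 1.35 to 4301 ± 443.6 FPKM (log2 change 9.50, SE 0.465, adjusted p = 2.23e-06), and was at 7581 ± 95.1 in melanin hind wings, 3204 ± 809.6 in the red region and 3056 ± 655 in the black region. Gene c21362_g2 went from 1.28 ± 0.488 to 1321 ± 345.4 FPKM (log2 change 9.17, SE 0.429, adjusted p = 1.78e-06), with 2128 ± 384.5 in melanin hind wings and 966.4 ± 104.7 and 1105 ± 114.5 in the red and black regions. Genes c18114_g1 and c17159_g1 were abundant at 5 d alone among the 7 groups, at 6604 ± 1599 and 1338 ± 65.2 FPKM. They fell to 2.62 ± 0.728 (log2 change -10.82, SE 0.999, adjusted p = 9.97e-05) and to 1.03 ± 0.714 FPKM (log2 change -9.41, SE 0.639, adjusted p = 1.4e-05).

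From 5 d to the ommochrome stage, 1373 genes changed, 937 higher and 436 lower, with a median shift of 0.24 log2. Median-of-ratios factors gave 656 higher and 725 lower, quantile normalization 794 and 711, and equal FPKM totals 1713 and 418. The count was 537 without ommochrome replicate 1, 720 without ommochrome replicate 2, 876 without 5 d replicate 2 and 846 in a fit to the hind wing libraries alone.

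**Figure D2:**
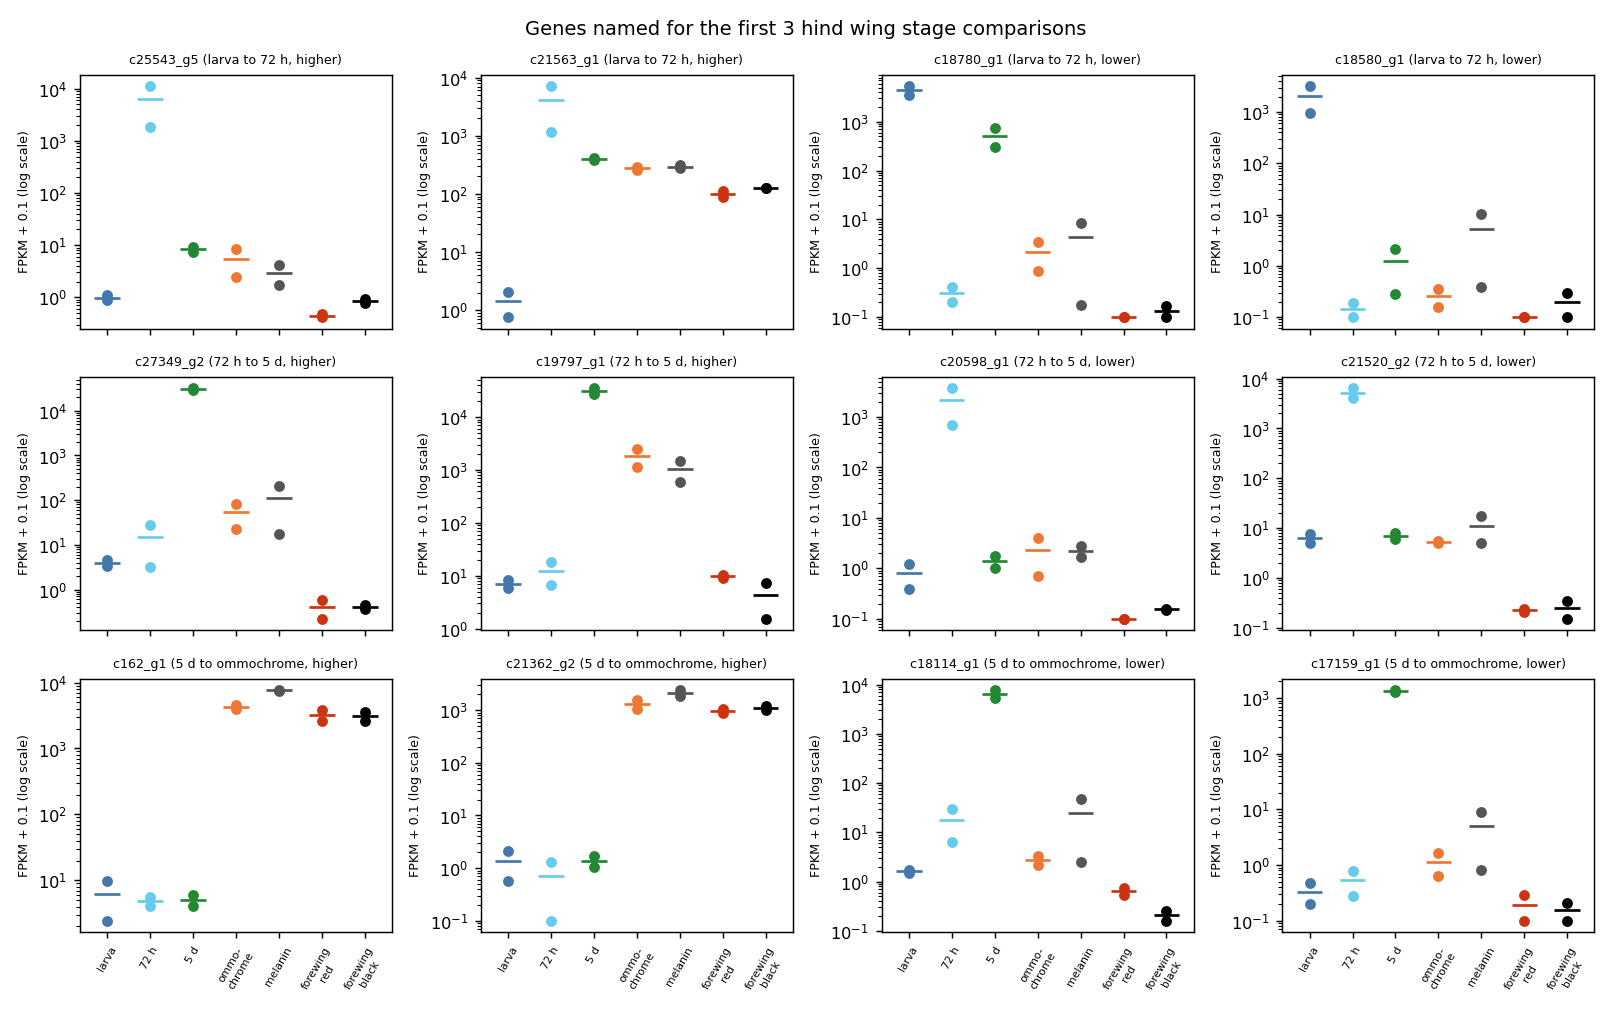
FPKM + 0.1 on a log axis of the 12 genes named for the first 3 hind wing steps, in the 7 groups. Points are libraries and bars are arithmetic group means plus 0.1; c27349_g2 and c19797_g1 reach 30311 and 31467 FPKM on average at 5 d.

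Few genes separated the ommochrome from the melanin stage of the hind wing, the step in which black pigment appears. Gene c24618_g10 was lowest at the ommochrome stage, at 3.44 ± 0.262 FPKM against 49 ± 5.79 at the melanin stage (log2 change 3.49, SE 0.525, limma adjusted p = 0.031). Its means were 43.3, 27.2 and 18.7 FPKM in larval, 72 h and 5 d hind wings and 44.9 and 30.7 FPKM in red and black regions. The 5 d libraries were far apart, at 30.24 and 7.19 FPKM. Gene c17113_g1 was at 4.16 and 17.99 FPKM in the melanin hind wings and at 0.16 or less in each of the other libraries (log2 change 3.24, SE 0.459, adjusted p = 0.0221). Gene c27787_g8 fell from 23.2 ± 0.0849 to 2.94 ± 2.96 FPKM (log2 change -2.86, SE 0.441, limma adjusted p = 0.0349). Its means in red and black regions were 34.8 and 63.4 FPKM. Gene c24647_g2 fell from 6.7 ± 2.83 to 0.47 ± 0.156 FPKM (log2 change -2.34, SE 0.292, limma adjusted p = 0.013), with 6.4 and 7.7 FPKM on average in red and black regions. These calls were lost in some limma fits with a single library left out: that of c17113_g1 without a red or ommochrome library (adjusted p 0.0613 to 0.196), and that of c24618_g10 without a red, larval, melanin or ommochrome library (adjusted p 0.0547 to 0.254). The call of c24647_g2 was lost without melanin replicate 1 or an ommochrome library (limma adjusted p 0.0616 to 0.158), and that of c27787_g8 without a black, red, 5 d, larval or ommochrome library (adjusted p 0.0501 to 0.272). In hind wings alone the calls of c17113_g1, c24618_g10 and c27787_g8 were lost (limma adjusted p = 0.166, 0.166 and 0.222), as were those of c17113_g1 with a pseudocount of 5 (adjusted p = 0.0892) and of c24647_g2 and c27787_g8 with a pseudocount of 0.1 (adjusted p = 0.147 and 0.246). Gene c17113_g1 fell below the filter, and so was not tested, without a melanin library or at a minimum of 5 FPKM. With the replicate number as a block, the call of c27787_g8 was lost.

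From the ommochrome to the melanin stage 27 genes changed, 13 higher and 14 lower, and 942 passed an unadjusted p of 0.05. With equal FPKM totals the split was 12 higher and 22 lower. By limma no gene (0) was called without ommochrome replicate 1 (635 at an unadjusted p under 0.05) or without ommochrome replicate 2 (498), 17 were called without red replicate 1 or without red replicate 2, and 59 without melanin replicate 2.

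The red and black regions of the forewing were compared to find genes that differ between regions of different colour within a wing. Colour and position in the wing changed together, so the 2 cannot be told apart. Gene c23707_g3 was at 1570 ± 27.7 FPKM in black and 149.1 ± 18.1 in red regions (log2 change 3.39, SE 0.573, adjusted p = 0.0268). Gene c28846_g6 was at 810.6 ± 16.7 FPKM in black and 77.8 ± 2.11 in red regions (log2 change 3.37, SE 0.381, adjusted p = 0.00356). In hind wings both lay under 6 FPKM up to 5 d, and c23707_g3 was at 90.7 ± 14.9 FPKM at the ommochrome and 332.9 ± 155.8 at the melanin stage. On the red side, c26211_g2 was at 62.5 ± 6.37 FPKM in red and 4.07 ± 0.997 in black regions (log2 change -3.66, SE 0.205, adjusted p = 8.16e-05), with 0.61 to 1.19 FPKM in the 4 ommochrome and melanin hind wing libraries and 0 in the 6 earlier ones. Gene c23145_g1 was at 74.8 ± 35 FPKM in red and 4.23 ± 3.85 in black regions (log2 change -4.01, SE 0.597, adjusted p = 0.0137), and at 78 ± 10.1 and 56.3 ± 4.71 FPKM in ommochrome and melanin hind wings. In limma fits with a single library left out, the call of c23707_g3 was lost without a forewing or ommochrome library (adjusted p 0.0534 to 0.227), that of c23145_g1 without black replicate 1 or a red library (adjusted p 0.0736 to 0.146), and that of c28846_g6 without red replicate 1 (adjusted p = 0.0503). With a pseudocount of 0.1 the calls of c23145_g1 and c23707_g3 were lost (limma adjusted p = 0.0703 and 0.263), and in the forewing libraries alone all 4 were lost (adjusted p 0.0885 to 0.376).

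In all, 81 genes differed between the regions, 22 higher in black and 59 higher in red. The median gene lay 0.155 log2 lower in black (-0.155), and 447 genes passed an unadjusted p of 0.05. Of the genes higher in black, 12 had at least 1 FPKM on average in melanin hind wings and 8 were under 1 FPKM in every hind wing library; of those higher in red, 36 and 16 did so. In limma's camera test, chosen after the data were seen, no difference between any of the 5 groups of stage genes and the other genes was called in the change between the regions. The smallest adjusted p was 0.168, for the larval group (adjusted p = 0.994 with an estimated correlation).

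The count rested on few libraries. It was 21 without black replicate 1, 23 without black replicate 2, 18 without red replicate 1 and 36 without red replicate 2. A limma fit to the 4 forewing libraries alone called 0 genes, with 1059 at an unadjusted p under 0.05. Deviations of same-numbered red and black libraries correlated at 0.43 across genes, so these libraries may be paired. Neither the main model nor the forewing fit allowed for that, and a replicate block in the forewings is given below.

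**Figure D3:**
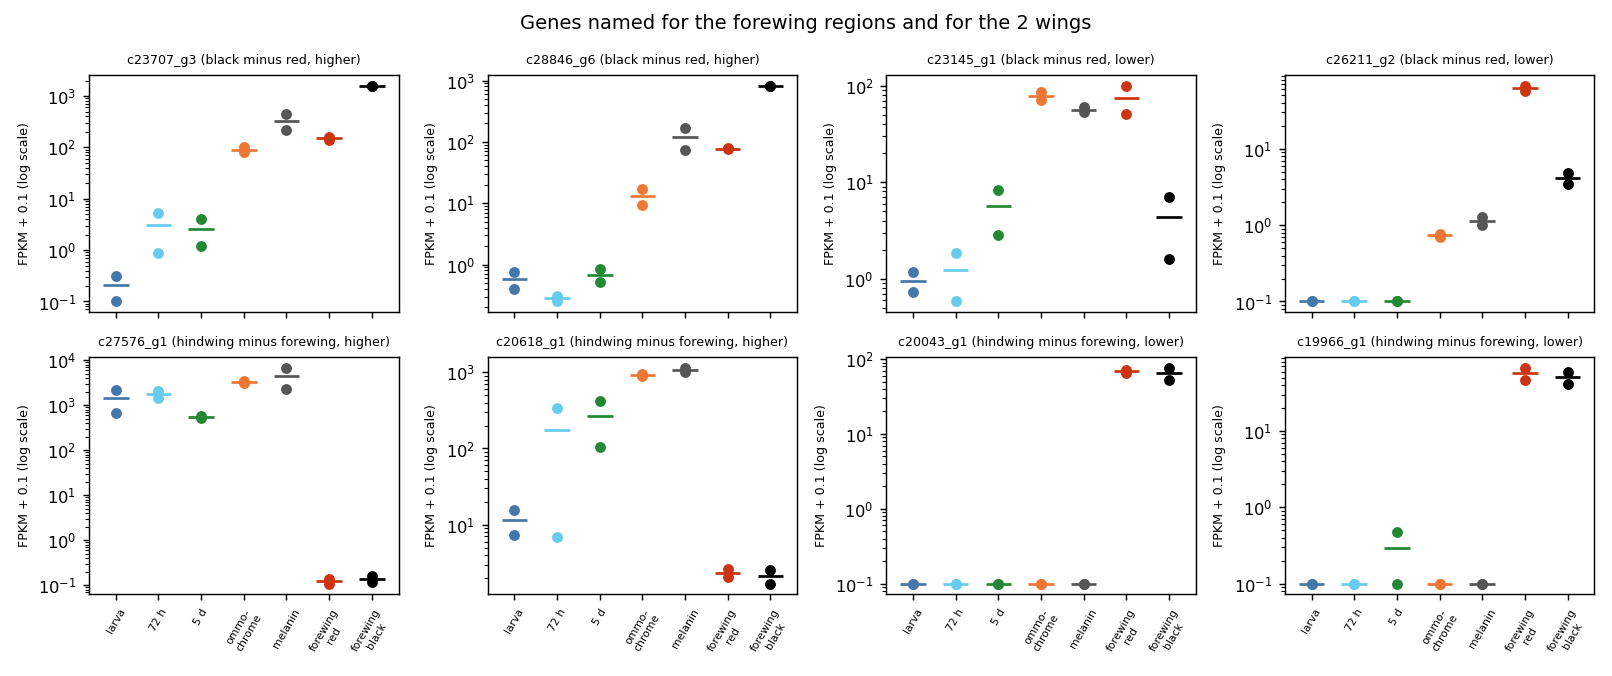
FPKM + 0.1 on a log axis of the 8 genes named for the forewing regions (top) and for hind wing against forewing (bottom), in the 7 groups. Points are libraries and bars are arithmetic group means plus 0.1; c27576_g1 has at most 0.06 FPKM in the forewing libraries.

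The difference between black and red regions was then set beside the step to the melanin stage in hind wings. A side of each comparison is named for black or melanin, and the comparisons share no library. Across the 10780 genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.0254 and a Spearman correlation of 0.0279. Without red replicate 1 the Pearson correlation was -0.00357, and without red replicate 2 it was 0.0417. Both changes were called higher by limma for 2 genes and both lower for none, in tests that share each gene's estimate of spread. No gene (0) was called in opposite directions. Independent lists would share 0.0265 genes called higher in both and 0.0766 called lower in both. The shared estimate of spread can raise such overlaps by itself, so the excess over 0.0265 was not tested. Those 2 genes were named after their values were seen. One was c28846_g6, which rose from 13.1 ± 5.64 to 121.8 ± 68.1 FPKM in hind wings (log2 change 3.06, adjusted p = 0.013). The other was c27080_g1, at 32.9 ± 10.2 FPKM in black and 7.96 ± 0.0636 in red regions (log2 change 1.89, adjusted p = 0.00862), which rose from 3.88 ± 1.11 to 17.2 ± 0.955 FPKM in hind wings (log2 change 1.92, adjusted p = 0.0165). As with all calls of that step, neither hind wing call was made by limma with an ommochrome library left out.

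Whole hind wings and dissected forewing regions labelled melanin stage were compared next, so wing and kind of sample changed together. The genes named for the largest changes were near 0 in one wing and abundant in the other. Gene c27576_g1 was at 6812 and 2329 FPKM in melanin hind wings and at most 0.06 FPKM in the 4 forewing libraries (log2 change 11.91, SE 0.486, adjusted p = 9.4e-07), and its means in the earlier hind wing stages were 543.7 to 3258 FPKM. Gene c20618_g1 was at 1081 ± 90.3 FPKM in melanin hind wings and 2.13 ± 0.447 (SD, n = 4) in forewings (log2 change 8.44, SE 1.16, adjusted p = 0.00147). In the other direction c20043_g1 was listed at 0 in all 10 hind wing libraries, against 72.5 and 65.9 FPKM in the red and 51.9 and 76.8 in the black regions. Gene c19966_g1 was listed at 0 in both melanin hind wings, at 0.38 FPKM in 5 d replicate 1 and at 0 in the remaining hind wing libraries, against 46.4 and 67.2 FPKM in the red and 41.6 and 58.9 in the black regions.

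Between the wings 2290 genes differed, 1640 higher in the hind wing and 650 higher in the forewing. Of these, 73 were higher and 31 lower in the hind wing by at least 3 log2, and the median absolute change of the called genes was 1.22 log2. The median of all genes lay 0.21 log2 higher in the hind wing. With median-of-ratios factors 1122 were higher and 1356 lower in the hind wing, and with quantile normalization 1015 and 1195. The count was 554 without melanin hind wing replicate 1, the library of lowest depth, 1355 without black replicate 1, 1264 without black replicate 2 and 1508 without red replicate 2. Against the ommochrome hind wing, a comparison chosen after the data were seen because of the conflict in the labels, the forewings differed in 1586 genes. Forewing means had a Spearman correlation of 0.902 with the ommochrome and 0.889 with the melanin hind wing. It was 0.652, 0.699 and 0.793 with larva, 72 h and 5 d. Estimated depths were 1.61 and 1.9 in the ommochrome and 0.461 and 1.29 in the melanin libraries. The ommochrome and melanin stages were thus not compared with the forewings at equal depth.

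**Figure D4:**
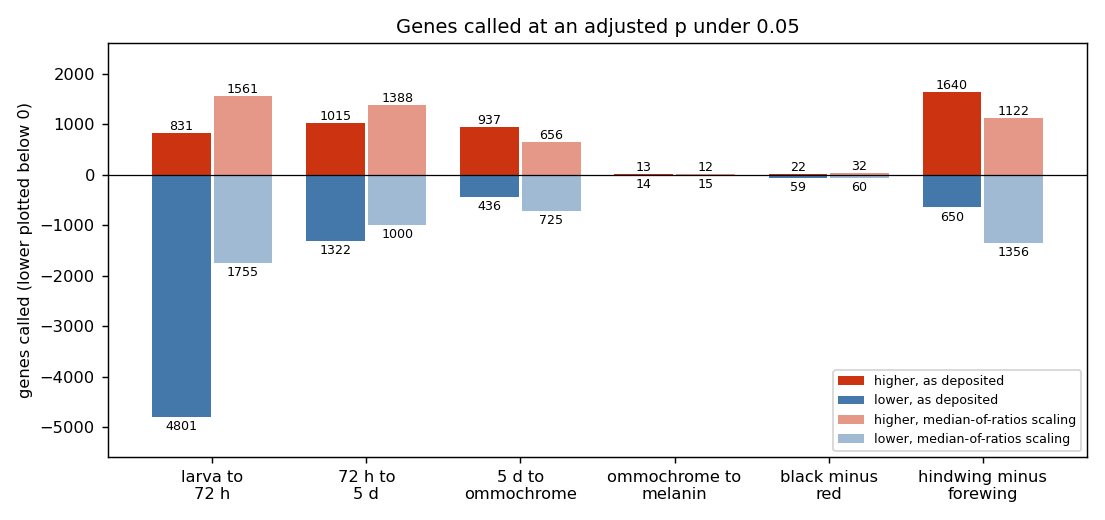
Genes called in each of the 6 comparisons, with higher genes above and lower genes below 0, from the deposited FPKM (solid bars) and after median-of-ratios scaling (pale bars). From larva to 72 h, 4801 genes are lower as deposited and 1755 after scaling.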

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

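The forewing replicate block, the ommochrome hind wing as the partner of the forewings, equal FPKM totals and leaving out the 10 most abundant genes of any library were alternatives chosen after the data were seen. Wherever the 10 most abundant genes of any library were left out, 51 genes were removed and the totals of the rest were also made equal. The 24 results on named genes kept their direction in all 600 values under alternatives; 552 stayed under an adjusted p of 0.05 and 48 did not. The direction was largely fixed by the rule that picked these genes, and fits in which a gene fell below the filter are not among the 600. The cause was not tested for the values that follow, except that the stricter filter tests fewer genes and that fits to fewer groups or without a library hold fewer samples. From larva to 72 h, 5632 genes became 3227 without the 10 most abundant genes, 3316 with median-of-ratios factors and 3499 with quantile normalization, and 4219 to 5757 with 1 library left out. From 72 h to 5 d, 2337 became 1526 in hind wings alone and 1647 to 2403 with 1 library left out. From 5 d to ommochrome, 1373 became 2131 with equal totals, 846 in hind wings alone, and 537 (without ommochrome replicate 1) to 1996 (without a 72 h library); it was 720 without ommochrome replicate 2 and 876 without 5 d replicate 2. From ommochrome to melanin, 27 became 13 with the filter at 5 FPKM, 13 with a pseudocount of 0.1, 48 with a pseudocount of 5, and 0 to 59 with 1 library left out; limma called 0 without ommochrome replicate 1 (635 at an unadjusted p under 0.05) or 2 (498), 17 without red replicate 1 or without red replicate 2 and 59 without melanin replicate 2. Between black and red, 81 became 53 with the filter at 5 FPKM, 36 with a pseudocount of 0.1, 0 in the limma fit to forewings alone (1059 unadjusted), and 18 to 96 with 1 library left out (21 and 23 without black replicates 1 and 2, 18 and 36 without red replicates 1 and 2). Between the wings, 2290 became 554 (without melanin replicate 1) to 3050 (without 72 h replicate 1), with 1355 and 1264 without black replicates 1 and 2 and 1508 without red replicate 2. Across the stages, 7624 became 6102 to 7990 with 1 library left out. The correlation of black against red with ommochrome to melanin, 0.0254, was 0.0389 without the 10 most abundant genes, 0.0383 with equal totals, 0.0394 with median-of-ratios factors, 0.0103 with no filter, 0.00318 with a pseudocount of 5, and -0.00357 to 0.0417 with 1 library left out. Where 1 library was left in a group, it was assumed to vary like the other groups.

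Replicate numbers paired no groups other than red and black. Deviations of same-numbered libraries correlated at over 0.1 in 1 of 21 pairs of groups (range -0.12 to 0.43), and 6 of 14 libraries correlated best with their own number. The 1 pair was red with black, at 0.43, so same-numbered red and black libraries may be paired, which the titles do not state. With the replicate block, the counts were 5605, 2279, 1374, 20, 71 and 2251 in the order above, 7544 across the stages, and the correlation was 0.0254. A replicate block in the forewings alone gave 83 genes between black and red, 18 higher and 65 lower. Of the named genes, c27787_g8 lost its call under the block. Alternatives for gene lists were not run, because no identifier has a name. Depth limits low genes most in melanin hind wing replicate 1, whose depth was 0.461 of that of larval replicate 1.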

Other observations

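The tests chosen after their results were seen were the median-of-ratios reading of the larval step, the depth of the 72 h libraries, the calls kept at 20 FPKM or more, the reference shares of hind wing stages outside the range of the others, and both tests of the low levels of 72 h genes. Equal FPKM totals, leaving out abundant genes and the ommochrome hind wing as a partner also used alternatives added after the data were seen.

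A small set of genes was measured in every library of one wing and near 0 in the other. In all 4 forewing libraries 11 genes had at least 5 FPKM while staying under 0.5 FPKM in all 10 hind wing libraries. The reverse held for 2 genes, c18819_g1 and c27576_g1. A hind wing gene had to reach 5 FPKM in 10 libraries of 5 stages, a forewing gene in 4 libraries of a single stage label. The counts of 11 and 2 are therefore not like for like. Gene c18819_g1 was singled out after its values were seen: it was at 72903 FPKM in 72 h replicate 1, at 8.39 to 40.2 FPKM in the other 9 hind wing libraries and at 0.13 to 0.34 FPKM in the forewings. It is among the 21 genes of 72 h replicate 1 treated last, so the doubt over their levels in other hind wings covers it.

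Among the 81 genes that differed between black and red regions, 12 shared an assembled component with another of them. There were 6 such repeats of a component, while 10000 random lists had a median of 0 repeats, and the middle 95% of them had at most 1. In 1 component the members went opposite ways: c23104_g1, chosen after its values were seen, was at 1397 ± 16.3 FPKM in black and 149.8 ± 13.4 in red regions, and c23104_g5 at 0.77 ± 0 and 8.3 ± 2.88. The summed FPKM of that component was 3.14 log2 higher in black, which is almost wholly the change of c23104_g1, so a division of reads between the members stays undecided.

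The 72 h hind wing libraries differed by more than 3 log2 in 333 genes, against 18 to 58 genes in the other 6 groups. In 72 h replicate 1, 21 genes with at least 1000 FPKM and at least 100 times their value in replicate 2 held 36.1% of the FPKM, 5 such genes held 15.5% in replicate 2, and no other library had any (0 by this count, with no test). Tests of this difference gave a correlation across genes of -0.167 with the change from larva to 5 d, a robust SD of 0.604 log2 against at most 0.543 in the other groups, and a relative depth of 1.05 in the more shallow library.

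It was asked whether genes higher in the red region fell, and genes higher in the black region rose, from the ommochrome to the melanin stage in hind wings. The median of the red list lay at percentile 16.73 and that of the black list at percentile 24.55 of 10000 random lists matched on mean expression. Both medians were 0, with 24 red-list genes lower and 28 higher and 6 black-list genes lower and 9 higher. The percentile bound set beforehand against the hypotheses was reached, but it cannot decide on them. In every hind wing library, 16 genes of the red list and 8 of the black list were under 1 FPKM. Such genes could hardly move and pull a median toward 0, while the members that moved went both ways. The random lists were matched on the mean over all 14 libraries, not on the hind wing level. Both hypotheses stay undecided.

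From larva to 72 h, 85.2% of called genes were lower. Different FPKM totals are argued against as the whole cause, because 79.6% were lower with equal totals, above the 75% set beforehand. The larger share held by a few abundant genes at 72 h could account for part of it. With the 10 most abundant genes of any library left out and totals also made equal, 60.7% were lower. That was just above the 60% set as the mark of that cause, and equal totals alone had given 79.6%. Median-of-ratios scaling gave 52.9%, but it centres the median gene and so cannot tell a shift of scale from a real fall of most genes. A developmental fall of most transcripts after the larval stage stays open and was not tested.

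The 2290 genes that differed between the wings at the labelled melanin stage became 554 without melanin hind wing replicate 1, a fall that had been set beforehand as the mark of that library's low depth. A later test took the 625 calls at a mean of 20 FPKM or more. Without replicate 1, 23.7% of them were kept, against 74.4% without replicate 2. This test cannot decide on low depth, because each fit leaves 1 melanin hind wing library. The threshold on p also tightens as the number of all calls falls, so abundant genes could lose their calls too. Low depth stays undecided, and what else may set melanin hind wing replicate 1 apart was not tested. A forewing time within the 5 sampled hind wing stages is undecided: 61.5% of the called genes had a forewing mean outside the range of the 5 stages, above the 50% set beforehand against it, but among genes called against a neighbour, hind wing stages inside the series gave 31.5% to 50.6%, and 63% for 27 genes, against the other 4 stages. For the ommochrome stage itself, the 1586 genes called against that hind wing lay between the bounds set for and against it. The labels name no batch (0), so a batch of forewing libraries and the biological difference between wings cannot be told apart. Hind wings were also taken whole and forewings as dissected regions, and that difference in sampling cannot be told apart from the wing either.

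The 21 genes extreme in 72 h replicate 1 kept a median of 0.0235% of that level in the 8 other hind wing libraries outside 72 h, against 0.000293% in the 4 forewing libraries. Reads of 72 h replicate 1 assigned to other libraries of a shared sequencing pool could give this, as could low expression in hind wings of every stage. Across the 21 genes, which are not independent, the level in the 8 libraries followed that in 72 h replicate 1 with a Pearson r of 0.501 (permutation p = 0.02) and a Spearman rho of 0.555 (permutation p = 0.01), and r was 0.37 without the 2 farthest genes; assigned reads had been taken to need 0.7. The shallowest of the 8 libraries had 1.6 times the median level of the other 7, between the 1.5 set for true expression and the 2 set against it. The 21 genes include some with high larval levels: c22809_g1 was at 2719 and 1029 FPKM in the larval libraries, and c24342_g1 at 3913 and 1011. The r therefore mixes such expression with any assigned reads. The 2 farthest genes were those farthest from the median level in 72 h replicate 1, not these larval genes by choice. Neither test decides, and the explanations cannot be told apart with these values.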
